A study of Mus musculus with 16 samples.

How the data were processed

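The series holds RNA-seq libraries of microglia from mouse brain, 4 per group and 16 in all. Groups were taken from the genotype labels and the title prefix: S302 wild types, S302 heterozygotes for the Hexb-tdTomato allele, S348 wild types and S348 homozygotes. Replicate numbers come from the titles for S302 and follow the order of the title numbers for S348. Per the labels' protocols, cells were kept in RNAprotect buffer and RNA was extracted with the RNeasy Plus Micro kit. First-strand cDNA was made from 500 pg of total RNA with the SMARTer Ultra Low Input kit and amplified over 12 PCR cycles, libraries were made with Nextera XT, and single reads of 50 cycles were taken on an Illumina HiSeq. Per the submitters' processing notes, STAR 2.7.2a, featureCounts 1.6.2 and limma were used on GRCm38.p6. The authors deposited 1 table of raw read counts per gene symbol, with gene coordinates and lengths per the file headers. The annotation release, the strand setting, the treatment of reads that fit several genes and any filter are not given in the sources used here. This kind of kit does not mark strand, so genes that overlap on opposite strands can exchange reads. PCR copies were not told apart, so floors, and any interval made from counts alone, cover counting error only.

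The deposited counts were used as they stand. Library sizes were the column totals, scaled by TMM, and CPM values are TMM-scaled unless they belong to a floor. The floor of a gene without counts was 3 counts in each library, and a fold against such a group is a bound made from unscaled CPM. Genes were kept by filterByExpr with a minimum count of 10, which left 13693 of 55341. The counts of 4 groups were fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, all 16 libraries sharing the spread), and p-values were adjusted by Benjamini-Hochberg at 0.05. Contrasts were heterozygotes against S302 wild types, homozygotes against S348 wild types, the difference of these, and S348 against S302 wild types. A further fit used the number of reporter alleles with the prefix as a term. Standard errors follow from the quasi-likelihood F value, and intervals are at 95%. Hexb and Gfm2 and 2 further genes also had a two-sided exact permutation test on log2 CPM over the 70 splits of 8 libraries.

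The named genes follow a rule fixed, with the tests, gene lists and main alternatives, before the data were examined. Hexb, Nnt and any reporter feature were always named. For each contrast, up to 10 genes in each direction were named by size of change among those past the threshold, with at least 5 CPM in a group and no overlap between the groups (the last not for the allele fit and the difference of effects). Where none passed, the 3 with the smallest p were named. Genes without an assigned symbol and pseudogenes were counted only, apart from CT010467.1 and Gm26917. For a list, up to 4 members past the threshold were named, or else the 2 most abundant. Hexa, CT010467.1, Gm26917 and the Gfm2 value between wild types were added after values were seen. C1qc, a homeostatic gene past the threshold between wild types, was named beyond the limit of 4.

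Gene lists covered homeostatic and disease-associated microglia, the type I interferon response, antigen presentation, inflammatory cytokines, immediate early genes, heat shock, glycosphingolipid degradation, the lysosome, the unfolded protein response, the cell cycle, cholesterol synthesis and efflux, mitochondrially encoded genes, cytosolic ribosomal proteins, sex-linked genes, C57BL/6 substrain genes and genes within 5 Mb of Hexb. Markers covered border-associated macrophages, monocytes, neutrophils, T and NK cells, B cells, astrocytes, oligodendrocytes, neurons, endothelial and mural cells, ependyma and choroid plexus, and erythroid cells. Of 28 lists, 27 had at least 3 tested members; the erythroid list did not and gave no test. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, and adjusted over the lists within a contrast.

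The scripts were tested on simulated counts with known changes. Of genes changed 2-fold, 82.1% were recovered for heterozygotes (13311 genes run), 76.1% for homozygotes (13298 genes) and 77.6% between wild types (13317 genes). At 1.5-fold the shares were 47.8%, 38.8% and 43.3%, and 3.82%, 6.58% and 5.77% of the calls were false. Each run changed 200 genes at once, all of at least 5 CPM, and simulated no outlying library. The heterozygote and homozygote runs called 157 and 152 genes, where the data gave 2 and 4. More calls loosen the p that the adjustment asks for, so these shares overstate recovery where few genes change. Replicates were compared before averaging: no pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom 14.3 to 44.6). On the first principal component of log2 CPM (12.9% of the variance), replicate 2 of the S302 wild types lay at -112, and every other library between -25.6 and 25.5.

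Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, DESeq2 1.42.0, limma voom with and without sample quality weights, no filter or a minimum count of 50, a fit of the 8 libraries compared, a minimum log2 change of 1, counts without sex-linked genes, the replicate numbers of S302 as a block, and each replicate left out in turn. Added after seeing the data were fits without the 4 libraries with over 100 CPM of neutrophil markers, with sex as a term, with robust quasi-likelihood, and on counts thinned to equal depth. Stretches of 50 bases shared between genes were searched in GENCODE transcripts of GRCm38 with Biostrings 2.70.1. No library was left out of the tests reported first.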

Results

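Microglia, the resident macrophages of the brain, were isolated from C57BL/6J mice that carried a Hexb-tdTomato reporter allele or none, and their RNA was sequenced. Hexb encodes the beta subunit of the lysosomal beta-hexosaminidases and is strongly expressed in microglia, and tdTomato is a red fluorescent protein. The 16 libraries formed 4 groups of 4. Libraries with the title prefix S302 came from wild types and from heterozygotes, with 1 reporter allele. Libraries with the prefix S348 came from other wild types and from homozygotes, with 2 reporter alleles. Total counts ran from 20.8 to 22.9 M in the S302 wild types, from 19.2 to 22.7 M in the heterozygotes, from 26.0 to 32.2 M in the S348 wild types and from 25.5 to 30.7 M in the homozygotes. Between 16213 and 18744 genes had a count in a library. Cst3, which encodes the protease inhibitor cystatin C, was the most abundant gene in each library, with 3.71% to 5.30% of the counts. Xist, the RNA of the inactive X chromosome of females, exceeded 10 CPM (counts per 1e6 counts) in 3 of the 4 S302 wild types and in 2 of the 4 libraries of each other group. Nothing in the labels says that the replicates of a group were separate animals, so p-values measure the spread between these libraries.

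The first question was what the reporter allele did to its own gene. Hexb transcripts stood at 25068 ± 2265 CPM in the S302 wild types and 12504 ± 328 CPM in the heterozygotes (SD, n = 4 each), so heterozygotes held 49.9% ± 1.31 of the wild-type level. In the S348 wild types Hexb stood at 22648 ± 272 CPM and in the homozygotes at 601 ± 10.3 CPM (SD, n = 4 each), or 2.65% ± 0.0453 of the wild-type level. Every heterozygous library, at 12070 to 12867 CPM, lay below every S302 wild type, at 22002 to 27187 CPM. Hexb made up 2.45% of the counts in the S302 wild types, 1.25% in the heterozygotes, 2.28% in the S348 wild types and 0.0609% in the homozygotes. The log2 fold change was -1.0035 (SE 0.049, edgeR adjusted p = 1.23e-09) in heterozygotes and -5.24 (SE 0.058, adjusted p = 8.35e-21) in homozygotes. A two-sided exact permutation test gave p = 0.0286 for each genotype, the smallest that 4 libraries against 4 allow. The libraries were thus ordered by Hexb as their genotype labels say. The homozygotes still had 15740 to 18990 Hexb counts per library. No tdTomato feature is among the 55341 gene symbols, and the reporter transcript was not analysed here.

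**Figure D1:**
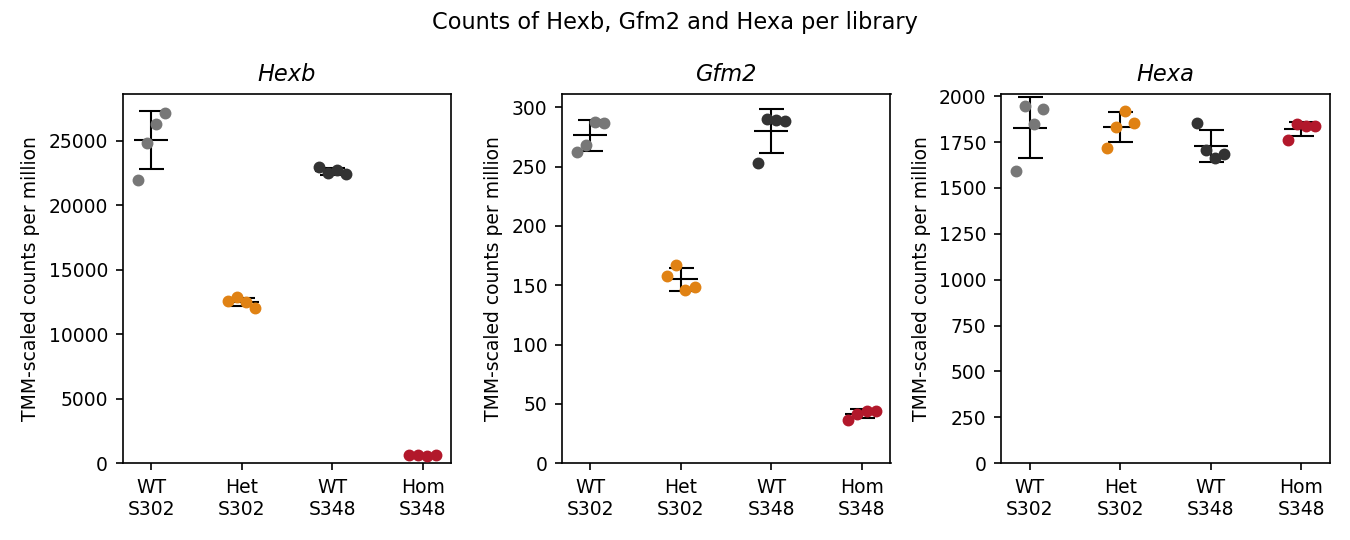
TMM-scaled CPM of Hexb, Gfm2 and Hexa (vertical axes, each starting at 0) in the 4 libraries of each group, with the group mean and SD as bars. Hexb and Gfm2 are lower in each library with a reporter allele than in each wild type of the same prefix, while Hexa stays between 1590 and 1946 CPM throughout.

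Gfm2, which encodes a mitochondrial ribosome recycling factor, changed in the same direction as Hexb. It stood at 276 ± 12.9 CPM in the S302 wild types and 155 ± 9.71 CPM in the heterozygotes, 56.1% ± 3.51 of wild type (SD, n = 4 each). In the S348 wild types it stood at 280 ± 18.4 CPM and in the homozygotes at 41.7 ± 3.66 CPM, 14.9% ± 1.31 of wild type (SD, n = 4 each). Its log2 fold change was -0.83 (SE 0.076, edgeR adjusted p = 2.01e-05) in heterozygotes and -2.75 (SE 0.081, adjusted p = 1.30e-13) in homozygotes. Hexb lies on chromosome 13 from 97176331 to 97198357 on the minus strand, and Gfm2 on the same chromosome from 97137937 to 97181195 on the plus strand (GRCm38). The genes overlap tail to tail over 4865 bases, 97176331 to 97181195. Of the 10685 exon bases of Gfm2, 3324 lie within the span of Hexb, 2709 of them in Hexb introns. Of the 1906 exon bases of Hexb, 615 lie in Gfm2 exons. The use of strand in counting is not given in the sources used here, so reads of the pair over the shared stretch cannot be told apart and the Gfm2 values are uncertain.

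**Figure D2:**
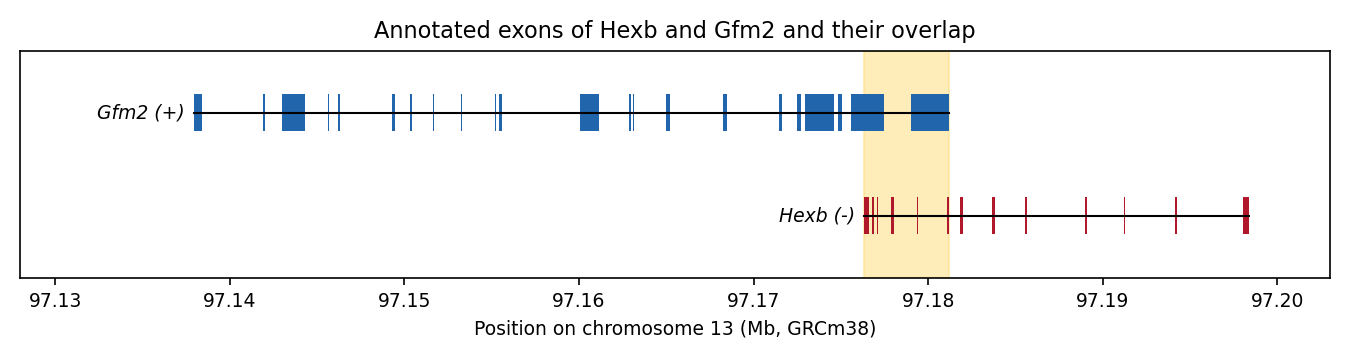
Map of the annotated exons (boxes) of Gfm2 and Hexb along chromosome 13 (horizontal axis, Mb, GRCm38), with the strand of each gene in brackets. The shaded stretch from 97176331 to 97181195 is where the genes overlap.

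Beyond this pair, heterozygous microglia differed little from the S302 wild types. Hexa, the alpha subunit that pairs with the Hexb product in beta-hexosaminidase A, stood at 1829 ± 165 CPM in wild types and 1831 ± 83.0 CPM in heterozygotes (SD, n = 4 each; exact permutation p = 0.971); it was singled out after its values were seen. Nnt, the mitochondrial transhydrogenase gene that is disrupted in the C57BL/6J substrain, stood at 79.4 ± 8.10 and 74.0 ± 6.6 CPM (SD, n = 4 each; exact permutation p = 0.314). Of 13693 genes tested, 2 passed an edgeR adjusted p of 0.05, Hexb and Gfm2, both lower. None passed as higher; the 3 with the smallest p in that direction were the ribosome assembly gene Ltv1 (log2 0.82, adjusted p = 0.200), the heme synthesis gene Hmbs (0.47, adjusted p = 0.626) and Tmem161b (0.96, adjusted p = 0.645). DESeq2 called 19 genes, 6 higher and 13 lower. At an unadjusted p under 0.05 there were 743 genes, against 684.7 in a test with no effect, and in 339 genes the groups did not overlap (2.48%, with 2.86% given by chance). Of 9396 genes with at least 5 CPM, 91.8% had a 95% confidence interval within 2-fold of no change.

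Among the gene groups, the type I interferon response leaned up in heterozygotes, with 28 of 34 members above 0 and a median log2 fold change of 0.16, but 0 members passed (edgeR; 6 at an unadjusted p under 0.05). Its most abundant members, Bst2 and Trim30a, stood at 86.2 and 78.5 CPM in wild types and at 102.2 and 76.8 CPM in heterozygotes. Heterozygous replicates 3 and 4 carried the lean, with list sums of 689.5 and 761.7 CPM against 517.1 to 613.7 CPM in wild types. Replicate 2 (509.9 CPM) lay below every wild type and replicate 1 (590.2 CPM) within their range. The list's camera adjusted p was 0.00551, and it was lost with an estimated correlation (adjusted p = 0.734). Neutrophil markers leaned down (camera adjusted p = 0.000216; adjusted p = 0.734 with an estimated correlation), with 0 of 6 genes past the threshold (edgeR; 0 at an unadjusted p under 0.05). These genes summed to 202, 0.246, 524 and 252 CPM in S302 wild-type replicates 1 to 4 and reached 213 CPM in heterozygous replicate 4, while heterozygous replicates 1 to 3 stayed at or below 0.106 CPM. The homeostatic microglia genes, such as Cst3 (46494 and 44292 CPM) and the growth factor receptor gene Csf1r (15682 and 15484 CPM in wild types and heterozygotes), were not called (adjusted p = 0.135), and neither were the lysosome genes (adjusted p = 0.990), the glycosphingolipid degradation genes (adjusted p = 0.895) or the disease-associated microglia genes (adjusted p = 0.896). Adjusted over the list alone, Cx3cr1 and Mog were called as lower and Kdr and Ly6a as higher, besides Gfm2. Leaving out the 4 libraries with neutrophil transcripts, an alternative chosen after seeing the data, raised the count of genes to 86, but only replicate 2 of the S302 wild types then remained; leaving out replicate 3 of the S302 wild types gave 4 genes.

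Homozygous microglia differed from the S348 wild types in 4 of 13693 genes. Besides Hexb and Gfm2, Cd34, which encodes a sialomucin of stem and endothelial cells that microglia also express, fell from 486 ± 47.6 to 319 ± 41.0 CPM (SD, n = 4 each; log2 -0.61, SE 0.095, edgeR adjusted p = 0.0253). Basp1, which encodes a membrane-bound signalling protein best known from neurons, rose from 347 ± 30.1 to 481 ± 44.9 CPM (SD, n = 4 each; log2 0.47, SE 0.078, adjusted p = 0.0395). In both genes the 4 homozygous libraries lay apart from the 4 wild types. Hexa stood at 1729 ± 86.8 CPM in wild types and 1821 ± 39.8 CPM in homozygotes (105.3% ± 2.30; exact permutation p = 0.143), and Nnt at 107 ± 6.00 and 95.9 ± 8.01 CPM (exact permutation p = 0.0571; SD, n = 4 each). At an unadjusted p under 0.05 (edgeR) there were 527 genes, against 684.7 in a test with no effect. In 443 genes the groups did not overlap (3.24%, with 2.86% given by chance). Of the 9396 genes with at least 5 CPM, 93.4% had an interval within 2-fold of no change. Cd34 and Basp1 were less firm than the Hexb pair. Only Hexb and Gfm2 stayed past the threshold without S348 wild-type replicate 3 or 4, without homozygous replicate 1 or 4, in a fit of these 8 libraries alone, or without the libraries with neutrophil transcripts (2 genes each). The last are all S302 and bear on this comparison only through the shared spread. Over 19 alternatives, which did not leave out single S302 libraries, Basp1 passed in 10 and Cd34 in 12. Basp1 was also lost on thinned counts and when any single S302 library other than wild-type replicate 2 was left out. Cd34 was kept in each of these. Adjusted p reached 0.268 for Basp1 and 0.163 for Cd34 over the 19, while the log2 fold changes hardly moved (Basp1 0.42 to 0.53, Cd34 -0.68 to -0.53). DESeq2 called 17 genes, 7 higher and 10 lower. Among them were the neutrophil genes Ltf, Ngp and S100a9, which had at most 1 count in any S348 library, so those calls rest on almost no counts.

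The homeostatic microglia genes lay slightly higher in homozygotes, with 27 of 30 members above 0 and a median log2 fold change of 0.06, though 0 passed singly (edgeR; 1 at an unadjusted p under 0.05). Cst3 stood at 38605 CPM in wild types and 41522 CPM in homozygotes, and Csf1r at 15105 and 15834 CPM. Homozygous replicates 2 to 4 had list sums of 174400 to 179800 CPM, against 162700 to 167200 CPM in wild types. Replicate 1 (162100 CPM) lay below every wild type. The S348 wild types were the lowest group, with a mean list sum of 164900 CPM against 173300 CPM in homozygotes. S302 wild types and heterozygotes stood at 181900 and 176000 CPM, so homozygotes did not exceed the range of the other groups. The list was called by camera (adjusted p = 0.0171) and lost with an estimated correlation (adjusted p = 0.812). Heat shock genes leaned up as well, with 8 of 11 members above 0 and 0 past the threshold (edgeR; 2 at an unadjusted p under 0.05): the chaperone genes Hsp90ab1 and Hspa8 stood at 798 and 252 CPM in wild types and at 1014 and 325 CPM in homozygotes (camera adjusted p = 0.0412; adjusted p = 0.812 with an estimated correlation). Genes within 5 Mb of Hexb were called as lower (camera adjusted p = 0.0171; adjusted p = 0.228 with an estimated correlation), where Gfm2 alone of 69 passed; without Gfm2 the camera p was 0.404. Lysosome genes (adjusted p = 0.333), glycosphingolipid degradation genes (0.350), interferon genes (0.350) and disease-associated microglia genes (adjusted p = 0.847) were not called. Neutrophil markers stayed at or below 0.111 CPM in each homozygote and S348 wild type. Endothelial and mural cell markers, of interest beside Cd34, summed to 70.4 ± 14.4 CPM (62.3 to 92.0) in wild types and 54.3 ± 3.69 CPM (50.1 to 59.1) in homozygotes (SD, n = 4 each). The list was not called (camera adjusted p = 0.479), with 2 of 5 members at an unadjusted p under 0.05 (edgeR). Only these 5 of the 19 listed markers passed the filter. S348 wild-type replicate 3 alone reached 92.0 CPM, with the other wild types at 62.3 to 63.7 CPM. The sum fell by far fewer CPM than Cd34, which went from 486 to 319 CPM. Fewer endothelial cells were not tested as a source of the Cd34 change, so a part played by them is not excluded.

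The effects of both genotypes were compared through their own wild types, because heterozygotes and homozygotes carry different prefixes. Hexb fell further in homozygotes than in heterozygotes by 4.23 on the log2 scale (SE 0.071, edgeR adjusted p = 1.31e-17), and Gfm2 by 1.92 (SE 0.109, adjusted p = 8.89e-09). No other gene passed over all genes tested. Adjusted over the list alone, Zfyve16, Polk and Kdr were called as lower and Mog as higher, besides Gfm2. On the same criterion, Zfyve16, Polk and Kdr were called as higher and Mog as lower in S348 than in S302 wild types. Both wild-type groups enter the difference, so for these genes a gap between the prefixes cannot be told apart from a genotype effect. Basp1 (log2 0.57, adjusted p = 0.320) and the calcium-dependent kinase gene Camk1d (0.63, adjusted p = 0.672) were nearest among those higher, with Shisa4, which stood at 0.565, 0.0243, 0 and 0.349 CPM in S302 wild types, heterozygotes, S348 wild types and homozygotes. For Basp1 the difference from heterozygotes passed with DESeq2 (log2 0.563, adjusted p = 0.00504) but in no other of 26 alternatives, and for Cd34 (log2 -0.54, edgeR adjusted p = 0.676) it passed in none. Homeostatic microglia genes had 28 of 30 members above 0 (median log2 difference 0.10; camera adjusted p = 0.00182; adjusted p = 0.670 with an estimated correlation), and 0 passed (edgeR; 2 at an unadjusted p under 0.05). This list also lay lower in S348 than in S302 wild types, and both wild-type groups enter the difference. Hexb and Gfm2 fell by near equal CPM steps per allele, Hexb to 49.9% and 2.65% and Gfm2 to 56.1% and 14.9% of wild type. Such steps give a larger log2 change for the second allele. Per reporter allele, with prefix as a term, Hexb changed by -2.31 (SE 0.181, edgeR adjusted p = 8.83e-07) and Gfm2 by -1.27 (SE 0.064, adjusted p = 8.46e-10) on the log2 scale. No other gene passed. Cd34 did pass per allele in some alternatives, such as no filter (log2 -0.2588, edgeR adjusted p = 0.0152) and DESeq2 (log2 -0.2607, adjusted p = 0.000757). The fit per allele assumes equal log2 steps, which Hexb did not show (-1.0035 with 1 allele, -5.24 with 2), so its slope for Hexb describes neither genotype. At an unadjusted p under 0.05 there were 630 genes for the difference and 589 per allele, against 684.7 in a test with no effect. Nearest among those higher were Klhl6 (log2 0.14 per allele), the autophagy gene Wipi1 (0.34 per allele) and Bst1, which stood at 0, 0.311, 0.0188 and 0.455 CPM in the order above (adjusted p = 0.672 for each of the 3). Without the libraries with neutrophil transcripts the difference between the effects covered 46 genes, 42 of them lower, again with replicate 2 alone for the S302 wild types; DESeq2 gave 16 genes for this difference (10 higher) and 9 per allele (3 higher).

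The wild types of both prefixes share a genotype, so their difference shows how far the S302 and S348 libraries lay apart without a reporter allele. It was far larger than either reporter effect: 238 genes passed, 113 higher and 125 lower in the S348 wild types. Among those higher were the DNA repair genes Slx4 (3.83 to 12.2 CPM, log2 1.67) and Wrn (7.89 to 21.1 CPM, log2 1.42), Zbtb41 (log2 1.21), the circadian activator gene Arntl (13.2 to 26.4 CPM, log2 1.00), Manea (1.00), Trim44 (1.00), Nbea (0.97), the chaperone cofactor gene Ahsa2 (0.95), Kyat3 (0.90) and the p53 inhibitor gene Mdm4 (0.89). Among those lower were the histone gene Hist1h4d (22.1 to 3.42 CPM, log2 -2.697), Lrmda (-2.14), the microRNA gene Mir6236 (-1.33), Rwdd3 (-1.27), Alg10b (-1.08), the circadian repressor gene Nr1d1 (18.5 to 9.66 CPM, log2 -0.94), the mitochondrial large ribosomal RNA mt-Rnr2 (560 to 294 CPM, log2 -0.93), Bysl (-0.86) and the mitochondrial leucyl-tRNA synthetase gene Lars2 (350 to 199 CPM, log2 -0.82). The edgeR adjusted p of these genes ran from 0.00313 for Hist1h4d and Lars2 to 0.0473 for Kyat3. Ltf, which encodes the neutrophil granule protein lactoferrin, had no count in the S348 wild types and was at least 473-fold lower there, against a floor of 3 counts per library. This rests on replicates 1, 3 and 4 of the S302 wild types, at 36.4 to 99.5 CPM of Ltf, since replicate 2 had 1 count, and Ltf passed in only 7 of 17 alternatives.

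Several of these genes may share reads with others, though sharing was not measured. Of the 50-base stretches of Hist1h4d transcripts, 10.2% occur in transcripts of other genes, most often the histone gene Hist1h4i, and 7.31% of those of Mdm4 occur elsewhere, mostly in its pseudogene. Nr1d1 overlaps Thra, Bysl overlaps Ccnd3 and Ahsa2 overlaps Usp34, each on the opposite strand, so these values are uncertain too. Nnt rose from 79.4 ± 8.10 to 107 ± 6.00 CPM (SD, n = 4 each; log2 0.43, adjusted p = 0.0281), while Hexb (log2 -0.15, adjusted p = 0.120), Hexa (-0.08, adjusted p = 0.551) and Gfm2 (0.02, adjusted p = 0.937) did not pass; Gfm2 turns to a log2 of -0.0011 with upper-quartile scaling. In 1145 genes the wild types did not overlap (8.36%, with 2.86% given by chance), and 2297 genes had an unadjusted p under 0.05. The number of genes rested on single libraries: it was 127, 116, 146 and 395 without S302 wild-type replicates 1 to 4, and 50, 56 and 89 without S348 wild-type replicates 2, 3 and 4. It was 66 in a fit of these 8 libraries alone, 100 with sample quality weights, 888 with DESeq2, and 325 (260 higher, 65 lower) without the libraries with neutrophil transcripts, where 59 of the 238 genes were still called.

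Gene groups leaned with the prefix as well: camera called 14 of 27 lists at the preset correlation, and 0 with an estimated correlation. Transcripts of the mitochondrial genome fell, with 6 of 8 genes past the threshold, among them the respiratory chain genes mt-Nd2 (144.8 to 88.7 CPM, log2 -0.71), mt-Co1 (285 to 187 CPM, log2 -0.61) and mt-Nd5 (186 to 122 CPM, log2 -0.60). mt-Nd3 had no count in the S348 wild types and was at least 8.93-fold lower there, and it also had none in homozygotes, against 0.678 CPM in heterozygotes. Beside mt-Rnr2, the ribosomal RNA gene CT010467.1 (284.5 to 83.7 CPM, log2 -1.76, adjusted p = 0.00152) and the noncoding gene Gm26917 next to it (659 to 180 CPM, log2 -1.87, adjusted p = 0.0164) fell as well. Both were singled out after their values were seen, and a difference in RNA quality or in ribosomal RNA carried into the libraries was not tested. Whether ribosomal RNA reads were counted in other genes called as lower, such as Mir6236 (annotated over 123 bases) and Lars2, was not tested either. Of the cytosolic ribosomal proteins, 5 of 81 fell, including Rps3a1 (log2 -0.55), Rps5 (-0.49), Rpl32 (-0.41) and Rps3 (-0.41), and 28 had an unadjusted p under 0.05; such genes have many processed copies in the genome. Of the lysosome genes, 6 of 45 fell, including the heparan sulfate hydrolase gene Naglu (log2 -0.50), Cd68 (-0.33), progranulin (Grn, -0.31) and Laptm5 (-0.30). Of the antigen presentation genes, Tapbp fell (685 to 537 CPM, log2 -0.35) and 16 of 17 members lay below 0. The camera adjusted p was 3.52e-15 for mitochondrial, 2.93e-09 for ribosomal, 2.87e-06 for lysosome and 2.78e-08 for antigen presentation genes. By fry 11 lists were called, and with an estimated correlation the adjusted p for these 4 was 0.0848, 0.113, 0.131 and 0.0848.

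Microglial genes moved in both directions between the wild types. Of 30 homeostatic genes, the TGF-beta receptor gene Tgfbr1 rose (1626 to 2538 CPM, log2 0.64) and 4 fell, Fcrls (-0.30), the complement genes C1qa (-0.29) and C1qc (-0.25), and Olfml3 (-0.27) (camera adjusted p = 0.0139; adjusted p = 0.297 with an estimated correlation). Of the disease-associated microglia genes, Cd9 (-0.48) and Cd68 (-0.33) fell (camera adjusted p = 0.0498, down, and adjusted p = 0.415 with an estimated correlation). The median of this list was -0.05 but its mean 0.27. That mean took in a highest fitted log2 of 7.53, and 1 member had no count in a wild-type group. The unfolded protein response list was called as higher, with Creld2 past the threshold (log2 0.49; camera adjusted p = 0.00624; adjusted p = 0.268 with an estimated correlation). Heat shock genes were called as higher (camera adjusted p = 0.00726; adjusted p = 0.323 with an estimated correlation), glycosphingolipid degradation genes as lower (0.0068; adjusted p = 0.131 with an estimated correlation) and cell cycle genes as lower (0.00601; adjusted p = 0.155 with an estimated correlation), each with 0 genes past the threshold (edgeR; 3, 5 and 4 at an unadjusted p under 0.05). The substrain list was called as higher with Nnt (camera adjusted p = 0.00636; adjusted p = 0.0848 with an estimated correlation). Interferon (adjusted p = 0.804) and inflammatory cytokine genes (adjusted p = 0.791) were not called. Single genes rose in lists that were not called: Myc among immediate early genes (log2 0.86; list adjusted p = 0.977), the cholesterol exporter gene Abca1 among cholesterol genes (0.68; list adjusted p = 0.354) and Fcho2 in the Hexb neighbourhood (0.53; list adjusted p = 0.128).

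**Figure D3:**
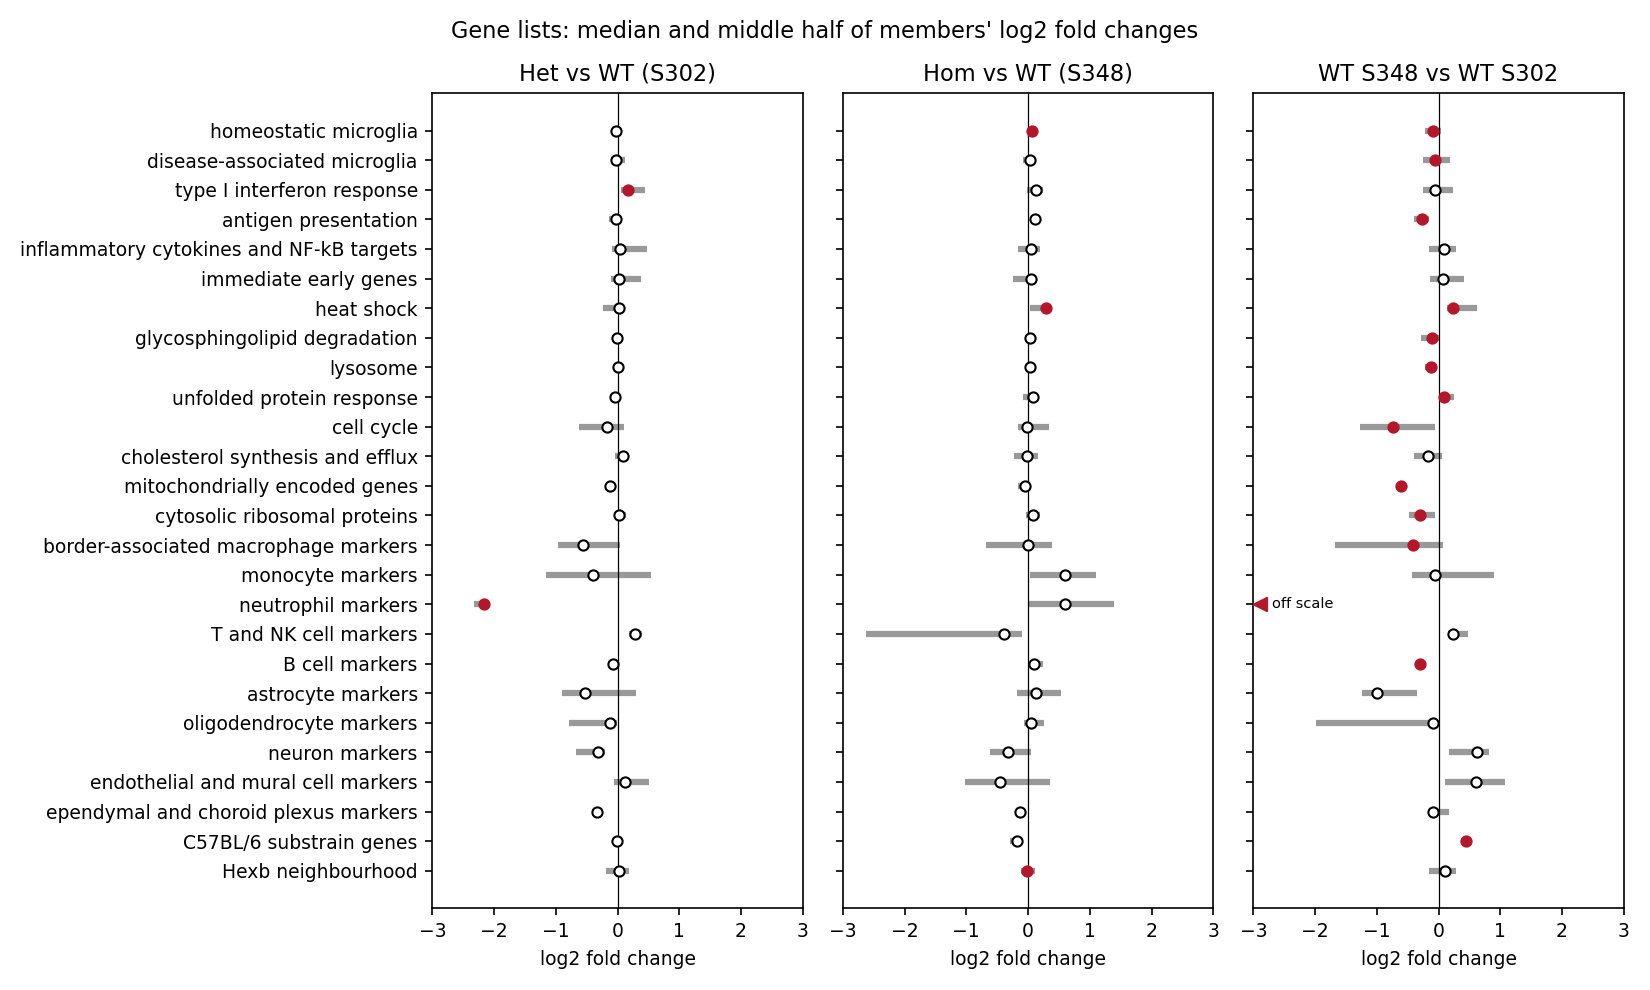
Median (circle) and middle 50% (grey bar) of the members' log2 fold changes (horizontal axes) for each gene list, in heterozygotes, homozygotes and between wild types, with filled circles for a camera adjusted p under 0.05 at the preset correlation of 0.01. Most medians lie near 0 for both genotypes, and neutrophil markers between wild types lie off scale, with a median of -9.69 when genes at 0 are set to the floor.

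Markers of other cell types were mostly scarce. Neutrophil markers summed to 245 ± 216 CPM in the S302 wild types and 0.0341 ± 0.0252 CPM in the S348 wild types (SD, n = 4 each), and 3 of 6 fell, Ltf, S100a8 (40.2 to 0.00761 CPM) and Lcn2 (12.6 to 0.00761 CPM). That list had a camera adjusted p of 6.09e-06 (adjusted p = 0.164 with an estimated correlation). Border-associated macrophage markers, such as Stab1 (161 and 170 CPM) and Mrc1 (20.6 and 18.004 CPM in S302 and S348 wild types), were called as lower with 0 genes past the threshold (edgeR; 4 at an unadjusted p under 0.05; camera adjusted p = 0.0267; adjusted p = 0.323 with an estimated correlation). The B cell list was called as lower, where the immunoglobulin gene Ighm fell (632 to 515 CPM, log2 -0.30; camera adjusted p = 0.0185; adjusted p = 0.131 with an estimated correlation). Markers of monocytes (adjusted p = 0.977), T and NK cells (0.796), astrocytes (0.495), oligodendrocytes (0.533), neurons (0.714), endothelial and mural cells (0.403) and ependyma and choroid plexus (0.580), and sex-linked genes (adjusted p = 0.825), were not called between wild types. Monocyte markers summed to 33.9 ± 22.7 and 12.3 ± 2.21 CPM, and neuron markers to 5.53 ± 1.71 and 6.82 ± 1.57 CPM in S302 and S348 wild types (SD, n = 4 each). Markers of the choroid plexus ranged widely within groups, from 0 to 74.0 CPM among S302 wild types.

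**Figure D4:**
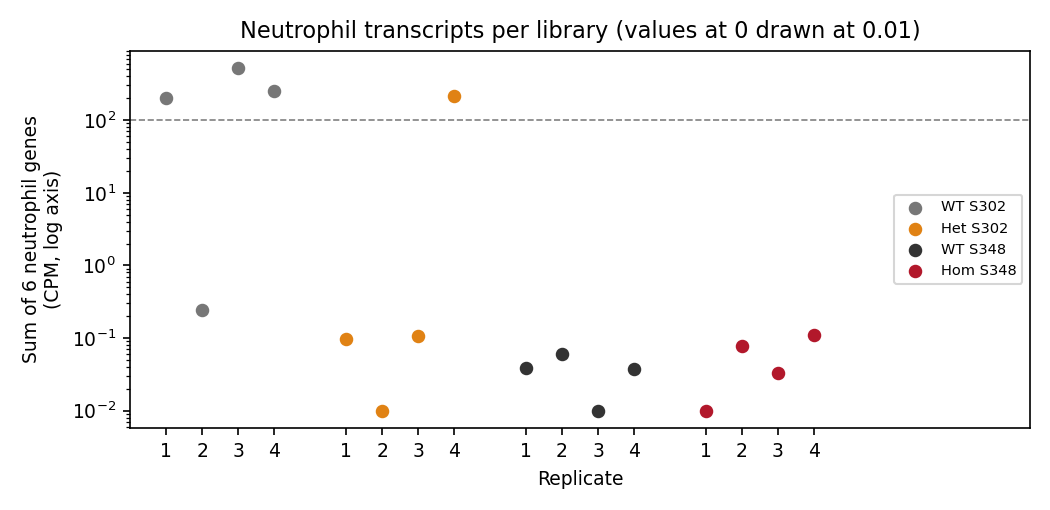
Sum of 6 neutrophil marker genes (vertical axis, CPM, log scale) in replicates 1 to 4 of each group, with values at 0 drawn at 0.01 and a dashed line at 100 CPM. Replicates 1, 3 and 4 of the S302 wild types and replicate 4 of the heterozygotes lie above the line, and every other library lies at or below 0.246 CPM.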

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

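The tests of carry-over, of Gfm2 against Hexb dose and neighbourhood, and of depth and sex were chosen only after the results they bear on were seen. The neutrophil test was set after the libraries with neutrophil transcripts and the genes called between wild types were seen, but before its own outcome. The other tests here were set before their own outcomes were seen.

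Hexb transcripts were left in homozygotes at 2.65% of the wild-type level, with little spread between the 4 libraries. Carry-over of wild-type S348 material, of both sexes, should have brought transcripts of the other sex (Xist into males, Y genes into females) to at least 1.33% of their normal level; the highest share in a homozygote was 0.341%, and in a wild type 0.309%, so carry-over is argued against as the main source. Reads of a near-identical gene are argued against as well, since 0 of 1903 stretches of 50 bases of Hexb transcripts occur in the 141658 transcripts of genes that do not overlap Hexb. Counts from the modified allele itself, such as exons left ahead of the reporter, stay open and were not tested, since the table holds 1 sum per gene.

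Gfm2 fell with the reporter allele. A change over the whole neighbourhood is argued against: the 68 other genes within 5 Mb had a median log2 fold change of -0.0108 in homozygotes, and 0 passed (edgeR). If Gfm2 counts were partly Hexb transcripts of the shared stretch, heterozygotes should lie at 56.2% of wild type, and if the modified chromosome made less Gfm2 they should lie at 57.4%; the observed 56.1% ± 3.51 (SD, n = 4) fits either. Homozygotes lost 239 CPM of Gfm2, or 1.08 for each 100 CPM of Hexb lost. The explanations cannot be told apart, because both follow allele dose and the counting gives no strand.

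The wild types differed in 238 genes. Depth is argued against as the whole cause, with 223 of them still called after thinning to equal depth. So is the number of males and females, with 153 still called with sex as a term, but less firmly. The bound set for sex was looser, and 153 genes would have missed the bound used for depth. Neutrophils in 3 S302 wild types are argued against for the set: in libraries free of neutrophil transcripts, whose means did not enter that contrast though they shared its estimate of spread (homozygotes against heterozygous replicates 1 to 3), 94.9% of the genes other than neutrophil markers (223 of 235) had the same sign. Library batch and animal cohort cannot be told apart, since 0 wild-type libraries separate them from the prefix. Other differences between the animals, and RNA quality, were not tested here and stay open.

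The libraries were regrouped to see how many genes other splits give. For homozygotes the real split gave 4 genes and the highest other 1, so that 1 of 35 splits reached the real count. Between wild types the real split gave 238 and the highest other 2, again 1 of 35. This share lies under 0.05 for both counts and is the smallest that 35 splits allow. The homozygote count includes Hexb, the modified gene, and Gfm2, which overlaps it. The splits therefore do not tell whether Cd34 and Basp1 passed by chance. For heterozygotes 2 of 35 splits gave 2 genes or more, and chance is not excluded for the count; the highest other, with 9 genes, put together exactly the 4 libraries with neutrophil transcripts. For the difference of the effects 5 of 100 splits reached 2 genes, with 4 as the highest other, and chance is not excluded for that count. Per allele 4 of 100 splits reached 2 genes, with 7 as the highest other, a share under 0.05. The 100 splits are a sample, so this share cannot be told apart from the 5 of 100 above. Chance is not excluded for this count either. For heterozygotes, the difference and the allele fit, the 2 genes called were Hexb and Gfm2. The splits compare numbers of genes and do not test these 2 genes singly.

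Among 193 groups of 4 libraries, 13 had a library that stood apart from the rest by Dixon's test at 0.05, where the gap is given as a share of the group's range and chance gives about 9.65. S302 wild-type replicate 2 stood apart in total counts (20.8 against 22.6 to 22.9 M, gap 0.880), Ltf (0.0493 against 36.5 to 103 CPM, gap 0.853), Nnt (67.4 against 81.4 to 84.4 CPM, gap 0.838) and neutrophil markers (0.246 against 202 to 524 CPM, gap 0.855). Heterozygous replicate 1 stood apart in Klhl6 (286 against 243 to 249 CPM, gap 0.854), inflammatory cytokines (1378 against 1580 to 1600 CPM, gap 0.947) and Shisa4 (0.0973 CPM against 0, gap 1), and heterozygous replicate 4 in neutrophil markers (213 against at most 0.106 CPM, gap 0.968). S348 wild-type replicate 1 was low in Gfm2 (253 against 288 to 290 CPM, gap 0.953), and replicate 3 was high in cholesterol genes (784 against 618 to 643 CPM, gap 0.831) and endothelial markers (92.0 against 62.3 to 63.7 CPM, gap 0.943). Homozygous replicate 1 stood apart in Hexa (1761 against 1840 to 1850 CPM, gap 0.890) and mitochondrially encoded genes (1852 against 1210 to 1290 CPM, gap 0.856). The effects of the genotypes differed for Hexb (-4.23) and Gfm2 (-1.92, log2, homozygous minus heterozygous), each past the threshold in the test of the difference. Near equal CPM steps per allele give such differences on the log2 scale.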

How the results depend on the processing

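The fits without neutrophil libraries, with sex as a term, with robust quasi-likelihood and on thinned counts were chosen only after the results were seen. Hexb and Gfm2 passed in heterozygotes, homozygotes, their difference and per allele under every alternative run, except that Gfm2 in heterozygotes did not reach a log2 change of 1. Of the counts and Hexb values, 139 stayed within 1.5 times or on their side of the threshold and 33 moved. Of the values of named genes, 1243 kept direction and side, 292 lost and 12 gained the threshold, and 10 changed sign; for lists these were 182, 30, 1 and 3. The median of all genes lay within 0.018 of 0 (log2) under each scaling. Where nothing else is said, the cause was not tested.

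With DESeq2 the counts were 19 for heterozygotes, 17 for homozygotes, 16 for the difference, 9 per allele and 888 between wild types, 232 of the latter shared. Without the libraries with neutrophil transcripts they were 86, 2 and 46 for the first 3, where the lone S302 wild type is assumed to vary like the other groups. A log2 change of at least 1, a stricter criterion, left 1, 2 and 34 genes in heterozygotes, homozygotes and wild types. Fitting only the 8 libraries gave 2 genes in homozygotes and 66 between wild types, where quality weights gave 100. Leaving out 1 replicate gave 2 to 4 genes in heterozygotes, 2 to 4 in homozygotes and 50 to 395 between wild types. With an estimated correlation 0 lists were called in any contrast, and with fry 0 for heterozygotes, homozygotes and their difference; camera at the preset correlation called 2, 3, 1 and 14 lists, the last between wild types.

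Values near 0 changed sign. Without the neutrophil libraries Nnt in heterozygotes was 0.11 (log2) and Hexa -0.088; Hexa was also -0.016 with quality weights and -0.014 with sex as a term. With 1 replicate left out, Hexa in heterozygotes ran from -0.057 to 0.033, being -0.019 without heterozygous replicate 3 and -0.0038 without replicate 4; Nnt in the difference ran from -0.124 to 0.0079, and Gfm2 between wild types from -0.0042 to 0.065. Gfm2 between wild types was -0.0011 with upper-quartile scaling. fry reversed the lysosome list in heterozygotes (adjusted p = 0.980) and the immediate early (0.894) and monocyte lists (adjusted p = 0.918) between wild types.

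The replicate numbers showed no clear pairing of the S302 libraries: same-numbered deviations correlated at -0.0615 to 0.315, over 0.1 in 2 of 4 pairs, and 1 wild type correlated best with its own number. With so few libraries this does not exclude pairing. With the numbers as a replicate block, 2 genes were called in heterozygotes, and Hexb was at -0.9993. Depth limits rare genes: 3 counts correspond to 0.0931 to 0.156 CPM.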

Other observations

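The test of clock genes was fixed before their values were seen, apart from Arntl and Nr1d1, which raised the question.

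Circadian regulators beyond the named genes were measured between the wild types. Clock, the partner of the Arntl product, rose in the S348 wild types from 16.5 to 29.1 CPM (log2 0.82, edgeR adjusted p = 0.0391). Dbp, a target that normally moves opposite to Arntl, stood at 19.1 and 10.5 CPM (log2 -0.86, adjusted p = 0.053) and Tef at 106 and 75.2 CPM (-0.49, adjusted p = 0.240), neither past the threshold. Bhlhe41 lay the other way (log2 0.40, adjusted p = 0.131), as did Per2 (0.64, adjusted p = 0.548), and Nfil3 (-0.07) and Cry1 (-0.03) lay near 0.

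A candidate explanation is that animals of the prefixes were taken at different times of day, which would move other clock genes in both arms. The medians of 3 positive-arm and 9 negative-arm genes, Arntl and Nr1d1 left out, differed by 0.19 (log2), where 95% of 10000 random sets of the same sizes and expression lay below 0.424 (permutation p = 0.230). The spread of the random sets was 0.245, so the bound set in advance was not missed by more than this spread, and with so few genes the time of day cannot be told apart from no effect. A p that misses the threshold does not exclude a difference in time of day, and the time of sampling is not in the labels.

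Beside Nnt, the substrain list held Wdfy1, at 75.6 ± 20.9 CPM in the S302 and 105.0 ± 14.7 CPM in the S348 wild types (SD, n = 4 each), called as higher when adjusted over the list alone. Oligodendrocyte markers were led by Trf (408 ± 17.4 and 391 ± 11.6 CPM) and astrocyte markers by Slc1a3 (265 ± 30.4 and 299 ± 23.5 CPM, same order, SD, n = 4 each), which microglia also express.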
